A study of Mus musculus with 6 samples.

How the data were processed

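RNA-seq libraries were analysed from muscle satellite cells, the stem cells of skeletal muscle that express the transcription factor Pax7. The cells came from wild-type C57Bl/6N mice on a high-fat diet or on chow, with 3 libraries per diet. Per the labels, at least 50000 cells were sorted by flow cytometry for each replicate, total RNA with an integrity number from 8.5 to 9.4 was used, ribosomal RNA was depleted during library preparation, and 75-bp single reads were sequenced. The labels do not say whether the replicates came from separate animals. The p-values therefore measure the spread between these libraries, which may be partly technical.

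The values were the deposited counts, 1 file per library, as whole numbers of reads per Entrez gene ID with no normalization. The submitters' processing notes name Bowtie2, featureCounts and the mouse builds GRCm38 and mm10, and versions, strand setting, treatment of multiply mapped reads and annotation release were not given in the sources used here. Each file held 27179 gene IDs. Of these, 25275 were matched to a symbol in the RefSeq gene table of GRCm38.p6 and 18 more through the GENCODE M21 gene metadata, and 1886 had no symbol. Coordinates are those of GRCm38.p6. Without a known strand setting, reads of overlapping genes cannot be told apart, and near-identical copies (ribosomal protein genes with processed pseudogenes, Hspa1a with Hspa1b) are uncertain. Total counts ran from 14930394 to 18217818 per library, so that a count of 3, used as the floor for a gene at 0, corresponded to between 0.165 and 0.201 CPM, counts scaled to a library of a fixed standard size. Floors cover counting error only, since molecular identifiers were not used here. No pair of libraries agreed within sampling noise, and all 6 were kept as separate replicates.

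Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10), library sizes were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood F test (glmQLFit, glmQLFTest, two-sided) compared high-fat diet with chow with diet as the only factor. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM as mean ± SD over 3 libraries. Principal components and correlations across genes used log2 CPM with a prior count of 2, the components on the 500 most variable genes.

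A total of 35 gene lists were fixed before the data were examined. They covered satellite cell state, cell cycle, metabolism, translation, stress, inflammation, matrix, signalling, markers of other cell types that a sort of muscle could hold, and sex-linked genes as a sample check. The 32 lists with at least 5 tested members (the sex-linked list aside) were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the lists. Camera asks whether members stand apart from the other genes. It was repeated with an estimated correlation, and fry, a rotation test of each list on its own, was run beside it. Members were counted both adjusted over all genes tested and adjusted over the list alone.

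Genes were named by a rule also fixed before the data were examined. Pax7, Myf5, Myod1 and Myog were always given. Of the changed genes with a mean of at least 2 CPM over the 6 libraries and no overlap between the diets, the 12 with the largest absolute log2 fold change per direction were named, leaving out predicted genes, RIKEN clones, pseudogenes and IDs without a symbol. Of each list, up to 4 changed members with the smallest p were named, or up to 2 members that did not pass where none did. Had fewer than 10 genes passed, the 10 with the smallest p would have been added. Xist and Ddx3y served as a sample check. Members named because they passed when adjusted over a list alone, the most abundant markers of other cell types, and other genes outside the rule were chosen after their values were seen.

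The alternatives planned before the data were examined were 3 other scalings, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without sample quality weights, robust dispersions, a test against a 1.5-fold change (glmTreat), an adjusted p under 0.1, the replicate number as a block, removal of mitochondrial genes, and leaving out each library in turn. Corrections for transcript length and GC content (a smoothed trend per library, span 0.3, removed as an offset), the fit without both libraries that stood apart, and 2 of the scalings for the lists were chosen after seeing the data.

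The test was checked on simulated counts for the same comparison, drawn for the 13202 tested genes from the real means, library sizes and fitted dispersions. In each of 5 runs 200 genes were changed 2-fold or 4-fold, and the members of a further gene list were shifted. It recovered 7.4% of genes changed 2-fold and 33% of genes changed 4-fold, and 31.8% and 90.8% of those above 50 CPM. Of its calls, 4.67% were false, where members of the shifted list counted as truly changed. A shifted list was called in 4 of 5 runs, and 0 of 155 unshifted lists were called. Genes were drawn independently and the lists were filled at random, so lists whose members vary together were not checked. The estimated correlation was 0.179 for the real list of immediate early genes and 0.846 for mitochondrially encoded transcripts. No library was left out of the analysis as reported. Results of some genes that the naming rule covers are not reported here.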

Results

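Gene expression was measured by RNA-seq in satellite cells sorted from the muscle of mice fed a high-fat diet (3 libraries) or chow (3 libraries). The series was designed to compare satellite cells of obese and lean mice. Gene counts summed to 14930394, 16432236 and 18217818 in high-fat diet libraries 1, 2 and 3, and to 15977166, 17025899 and 17690342 in chow libraries 1, 2 and 3. Transcripts of the mitochondrial genome took 9.31% ± 1.42 of counts with the high-fat diet and 8.33% ± 0.173 with chow (SD, n = 3 each). The share was 7.72%, 10.5% and 9.76% in high-fat diet libraries 1, 2 and 3, and 8.13%, 8.46% and 8.39% in the chow libraries. High-fat diet library 1 thus lay below every chow library. A single gene ID without a symbol took 11.2% ± 1.82 with the high-fat diet and 10.8% ± 0.982 with chow. Ddx3y, a gene of the Y chromosome, lay between 303 and 586 CPM in the 6 libraries, and Xist, the RNA of the inactive X chromosome, between 0 and 8.78 CPM.

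The diets were ordered along the first principal component of the most variable genes but did not form separate groups. This component held 29.4% of the variance and the second 27.0%. On the first, the high-fat diet libraries (-43.1, -12.3 and -11.9) all lay below the chow libraries (-0.142, 6.64 and 60.8), an order that chance gives in 10% of splits of 3 against 3. Its range came mostly from high-fat diet library 1 and chow library 3, which stood apart from the other 4. The correlation across these genes averaged 0.00571 ± 0.132 (SD, 6 pairs) within diets and -0.0912 ± 0.119 (SD, 9 pairs) between diets, a difference of 0.0969 that was smaller than either spread. Genes are not independent replicates, and no test was made of this difference. Over all tested genes, correlations between libraries ran from 0.73 to 0.84. The spread between libraries was wide, with a common biological coefficient of variation of 82.6% in edgeR (dispersion 0.682). For genes over 50 CPM the median dispersion was 0.0557.

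**Figure D1:**
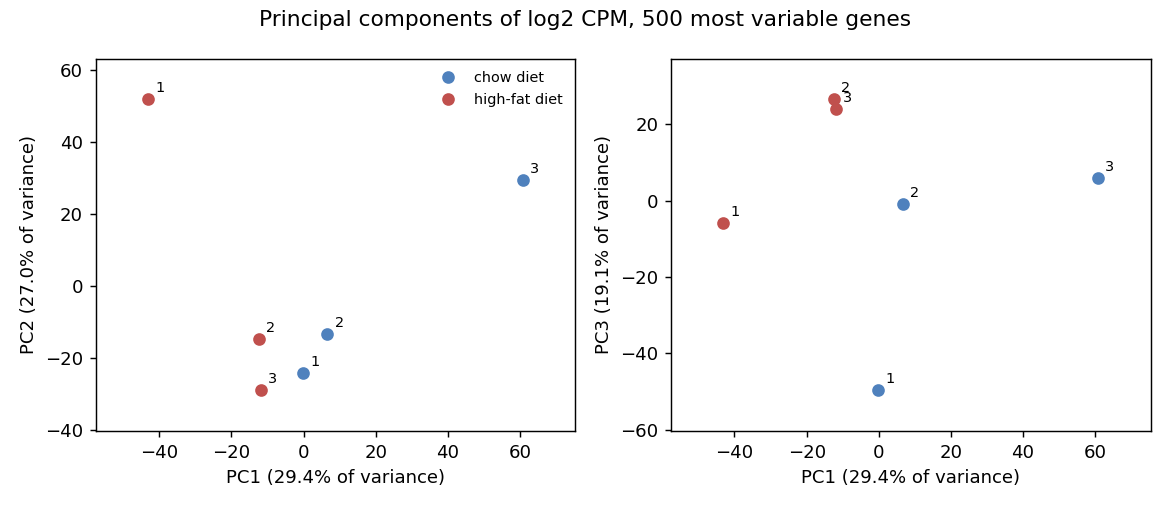
Each point is 1 library, numbered by replicate, on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM over the 500 most variable genes, in arbitrary units with the share of variance on each axis. High-fat diet library 1 (-43.1) and chow library 3 (60.8) lie at opposite ends of the first component, and component 3 holds 19.1% of the variance.

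The comparison of the diets asked which transcripts of satellite cells differed between obese and lean mice. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, rose 8.23-fold with the high-fat diet, from 28.1 ± 12.4 to 231 ± 54.6 CPM (SD, n = 3 each). Dio2, the deiodinase that makes active thyroid hormone, rose 7.63-fold, and Ucp2, a carrier of the mitochondrial inner membrane, rose 6.09-fold. Cyp51, a demethylase of cholesterol synthesis, was 5.43-fold lower. The immediate early transcription factors Nr4a1, Fos and Egr1, which cells induce within minutes of a stimulus, were 3.62-fold, 2.80-fold and 2.51-fold lower.

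In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of Angptl4 (chromosome 17, 33774900 to 33781575, GRCm38) was 3.04 (SE 0.31, adjusted p = 0.00197). Dio2 (chromosome 12, 90724552 to 90739038) changed by 2.93 (SE 0.34, adjusted p = 0.00297), from 33.2 ± 14.5 to 253 ± 98.9 CPM. Ucp2 (chromosome 7, 100493337 to 100499629) changed by 2.61 (SE 0.42, adjusted p = 0.0224), from 12.8 ± 7.14 to 78.1 ± 3.10 CPM. Cyp51 (chromosome 5, 4080674 to 4104697) changed by -2.44 (SE 0.29, adjusted p = 0.00297), from 122 ± 29.95 to 22.5 ± 4.85 CPM. Nr4a1 (chromosome 15, 101253902 to 101274795) changed by -1.85 (SE 0.21, adjusted p = 0.00297), from 735 ± 127 to 203 ± 52.7 CPM.

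Of 13202 genes tested, 34 passed an adjusted p of 0.05, 12 higher and 22 lower with the high-fat diet, and 1010 had an unadjusted p under 0.05. The 3 values of each diet did not overlap for 2018 genes (15.3%, where 10% arise by chance) and for all 34 changed genes. The count changed when 1 library was left out, in fits that had fewer libraries and tested 13845 to 14247 genes after filtering anew. It was 18, 9 and 44 without high-fat diet library 1, 2 or 3, and 19, 10 and 10 without chow library 1, 2 or 3. Without both libraries that stood apart the count was 1. It was 279 with DESeq2 (117 higher, 162 lower), 99 with limma-voom (44 higher, 55 lower), 163 with no filter on low counts, and 6 when tested against a 1.5-fold change. In each of the 6 fits with 1 library left out 8 genes passed, among them Angptl4, Dio2, Cyp51, Nr4a1, Egr1, Btg2 and Bhlhe40, and all 34 kept their direction in those fits.

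**Figure D2:**
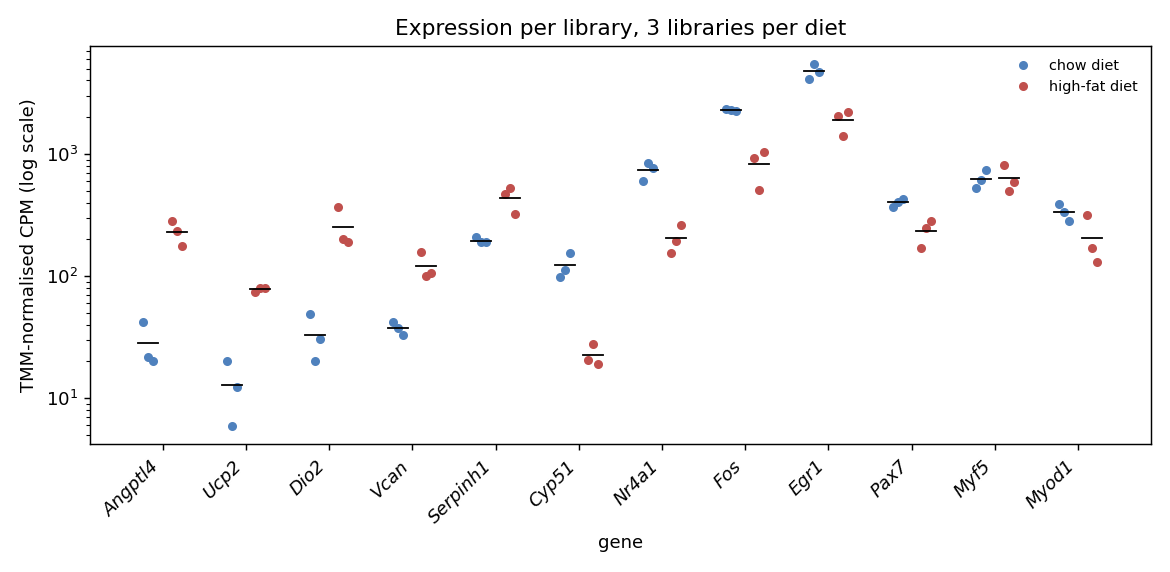
Points are TMM-normalised CPM of single libraries on a log axis for 12 genes, 3 per diet, and black lines are the means of each diet. The diets do not overlap for Angptl4 (231 against 28.1 CPM) or Cyp51 (22.5 against 122 CPM), whereas they overlap for Myf5 (633 against 623 CPM).

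The other named genes that rose changed by smaller amounts. Vcan, the matrix proteoglycan versican, rose 3.24-fold (37.4 ± 4.38 to 121 ± 32.3 CPM, adjusted p = 0.0194), and Serpinh1, a collagen chaperone of the endoplasmic reticulum, rose 2.25-fold (195 ± 11.0 to 439 ± 106 CPM, adjusted p = 0.0298). Igfbp4, which binds insulin-like growth factors, rose 2.82-fold (adjusted p = 0.0468), and Gfra1, a receptor of glial cell line-derived neurotrophic factor, rose 2.29-fold (adjusted p = 0.0473). The log2 fold changes of the lipase gene Abhd2, the septin gene Septin8, the mechanically gated channel gene Piezo1 and the cytolinker gene Plec were 1.08 (SE 0.19), 1.06 (SE 0.20), 0.86 (SE 0.16) and 0.81 (SE 0.14). The twelfth was an ID without a symbol. These calls and that of Ucp2 passed in at most 2 of the 6 fits with 1 library left out. Their direction held in all 6. Ucp2 and Vcan passed only without high-fat diet library 3 or chow library 1, with log2 fold changes over the 6 such fits from 2.26 to 3.10 and from 1.47 to 1.82. Igfbp4, Gfra1 and Septin8 passed in 0 of the 6 fits, with ranges from 1.23 to 1.70, 1.13 to 1.28 and 0.92 to 1.20. Gfra1, Septin8, Piezo1 and Plec did not pass with the length correction. Piezo1 overlaps Ctu2, Vcan overlaps Gm4117, Gfra1 overlaps Gm10007 and Plec overlaps Mir1942, so that their reads are uncertain.

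The list of immediate early and dissociation stress genes was called lower by camera (adjusted p = 1.09e-35), but not with an estimated correlation (adjusted p = 0.0793). Of 34 members tested, 9 fell in the test over all genes and 21 were lower adjusted over the list alone, with no member higher in either. The median log2 fold change was -0.81, and 31 of 34 members were negative. Besides Nr4a1, Egr1 fell from 4744 ± 670 to 1888 ± 425 CPM (adjusted p = 0.00474), Fos from 2297 ± 59.1 to 819 ± 277 CPM (adjusted p = 0.00947) and Btg2, an antiproliferative gene, from 421 ± 0.965 to 136 ± 43.1 CPM (adjusted p = 0.00521). Atf3, a stress-induced transcription factor, had a log2 fold change of -1.67 (SE 0.27, adjusted p = 0.0224), and Zfp36, which binds and destabilises AU-rich messenger RNAs, one of -1.27 (SE 0.19, adjusted p = 0.0102). The list also holds 5 heat-shock genes, with a median log2 fold change of -1.26, of which 0 passed over all genes in edgeR, 1 passed with DESeq2 and 3 with limma-voom, and 3 were lower adjusted over the list alone. Hspa1a was at 4677 CPM with chow and 1941 CPM with the high-fat diet, Hspa1b at 5130 and 2149 CPM and Dnajb1 at 513 and 170 CPM (edgeR adjusted p = 0.148, 0.159 and 0.0592 over all genes). Fos did not pass without chow library 3, Zfp36 without high-fat diet library 2 or chow library 2 or 3, and Atf3 without high-fat diet library 2 or any 1 of the chow libraries, with a highest adjusted p of 0.0641, 0.0869 and 0.128.

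The list of fatty acid and sterol synthesis genes was called lower by camera (adjusted p = 8.66e-11), but not with an estimated correlation (adjusted p = 0.0793). Its sterol members had a median log2 fold change of -1.19 and its fatty acid members one of -0.21, a division made after the values were seen. Of 33 members tested, 2 fell in the test over all genes, Cyp51 among them, and 10 were lower and 1 higher adjusted over the list alone. The lower ones included Sqle (81.1 to 29.2 CPM, log2 fold change -1.47, SE 0.33) and Hmgcs1 (97.9 to 30.7 CPM, -1.67, SE 0.40), whose adjusted p over all genes were 0.126 and 0.165. The higher one was Elovl1, an elongase of long fatty acids (16.1 to 38.7 CPM). The median log2 fold change of the whole list was -0.65. Fasn, the fatty acid synthase, was at 179 CPM with chow and 169 CPM with the high-fat diet (log2 fold change -0.08, SE 0.19, adjusted p = 0.999).

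Interferon response genes had a median log2 fold change of -0.79 over 34 members, of which 31 were negative. With edgeR 0 of 34 passed over all genes (10 had an unadjusted p under 0.05, and 3 passed with DESeq2 and 1 with limma-voom), and 7 were lower adjusted over the list alone. Among these, the transcription factor Irf1 went from 109 ± 23.7 to 51.8 ± 7.34 CPM and Irf9 from 57.8 ± 8.15 to 19.5 ± 8.11 CPM (adjusted p = 0.163 and 0.171 over all genes). Camera called the list lower (adjusted p = 5.87e-09), and the call was lost with an estimated correlation (adjusted p = 0.0959). Rnf213, an interferon-inducible ubiquitin ligase outside the list that overlaps Mir1932, fell 2.50-fold (569 ± 69.5 to 228 ± 60.2 CPM, adjusted p = 0.0143). It did not pass without high-fat diet library 1 or 2 or chow library 2 or 3 (highest adjusted p = 0.114).

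Cytosolic ribosomal protein genes had log2 fold changes that were small and mostly of the same sign. Of 63 members, 59 were negative with a median of -0.39. In edgeR 0 passed over all genes, 20 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 4 and 1. Adjusted over the list alone 3 were lower, namely Rplp0 (482 ± 60.8 to 279 ± 27.5 CPM), Rps4x (181 ± 7.09 to 102 ± 24.95 CPM) and Rpl5 (214 to 134 CPM). The list stood apart in camera (adjusted p = 1.27e-11) but not with an estimated correlation (adjusted p = 0.159). Many of these genes have processed pseudogenes, and how the counting treated shared reads was not given in the sources used here.

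The glucocorticoid response list, with 18 members negative and 2 positive, was called lower by camera (adjusted p = 0.000589), but not with an estimated correlation (adjusted p = 0.159). Of 20 members, Mt1, a metallothionein, fell 2.13-fold (998 ± 77.4 to 468 ± 125 CPM, adjusted p = 0.0326) and the transcription factor gene Cebpd fell 2.31-fold (523 ± 35.0 to 226 ± 77.5 CPM, adjusted p = 0.0373), while Angptl4 rose. Adjusted over the list alone, 5 were lower, with Errfi1, Foxo1 and Mt2 added, and Angptl4 was higher. The median log2 fold change was -0.39. Mt1 did not pass without high-fat diet library 2 or any 1 of the chow libraries, and Cebpd, which overlaps Spidr, passed only without high-fat diet library 3 (highest adjusted p = 0.184 and 0.218). Mt1 was also lost with the length correction.

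The list of fatty acid oxidation genes and PPAR targets was called higher by camera (adjusted p = 0.00496), but not with an estimated correlation (adjusted p = 0.132). Angptl4 and Ucp2 rose, 31 of 33 members did not pass over all genes in edgeR, and Cpt1a, which controls fatty acid entry into mitochondria, also passed adjusted over the list alone, where 3 were higher (65.7 to 147 CPM, log2 fold change 1.16, SE 0.30, adjusted p = 0.187 over all genes). The median log2 fold change was 0.01 and the mean 0.21.

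Extracellular matrix and TGF-beta response genes had a median log2 fold change of 0.31, with 30 of 43 members positive. Over all genes 0 of 43 passed in edgeR (15 had an unadjusted p under 0.05, and 4 passed with DESeq2 and 2 with limma-voom), and adjusted over the list alone 7 were higher and 1, Tgfb2, was lower. The basement membrane collagen gene Col4a1 went from 316 ± 19.7 to 526 ± 21.7 CPM (adjusted p = 0.0855 over all genes) and Loxl2, which cross-links collagen, from 108 ± 24.5 to 219 ± 16.7 CPM (adjusted p = 0.0882). Col4a1 overlaps Col4a2, so that its reads are uncertain. Camera called the list higher (adjusted p = 0.000589), and with an estimated correlation it was not called (adjusted p = 0.105). Fibroblast markers, which share collagen genes with this list, were not called (adjusted p = 0.566), and their most abundant member Serping1 was at 638 ± 29.0 CPM with the high-fat diet and 421 ± 19.2 CPM with chow.

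All 13 mitochondrially encoded transcripts had positive log2 fold changes, with a median of 0.28. Over the list's alternatives the median ran from 0.199 to 0.451. High-fat diet library 1 had a lower share of mitochondrial counts (7.72%) than every chow library. That share also counts the mitochondrial ribosomal RNAs, which the list leaves out, so it does not show how the 13 members behaved in this library. For the 2 members with the smallest p, ND1 (4309 CPM) and ND2 (3309 CPM), high-fat diet library 1 lay above all chow values, of which the highest were 3872 and 3173 CPM. Over all genes 0 of 13 passed in edgeR (5 had an unadjusted p under 0.05, and 1 passed with DESeq2 and 3 with limma-voom), and ND1, ND2 and ND5, subunits of respiratory complex I, were the 3 that were higher adjusted over the list alone. ND1 was at 3746 ± 133 CPM with chow and 5140 ± 720 CPM with the high-fat diet (log2 fold change 0.46, SE 0.13, adjusted p = 0.268). Camera called the list higher (adjusted p = 0.000589), whereas neither an estimated correlation (adjusted p = 0.618) nor fry (adjusted p = 0.384) did. The nuclear-encoded genes of oxidative phosphorylation had a median of 0.05 over 41 members and were not called (adjusted p = 0.619).

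**Figure D3:**
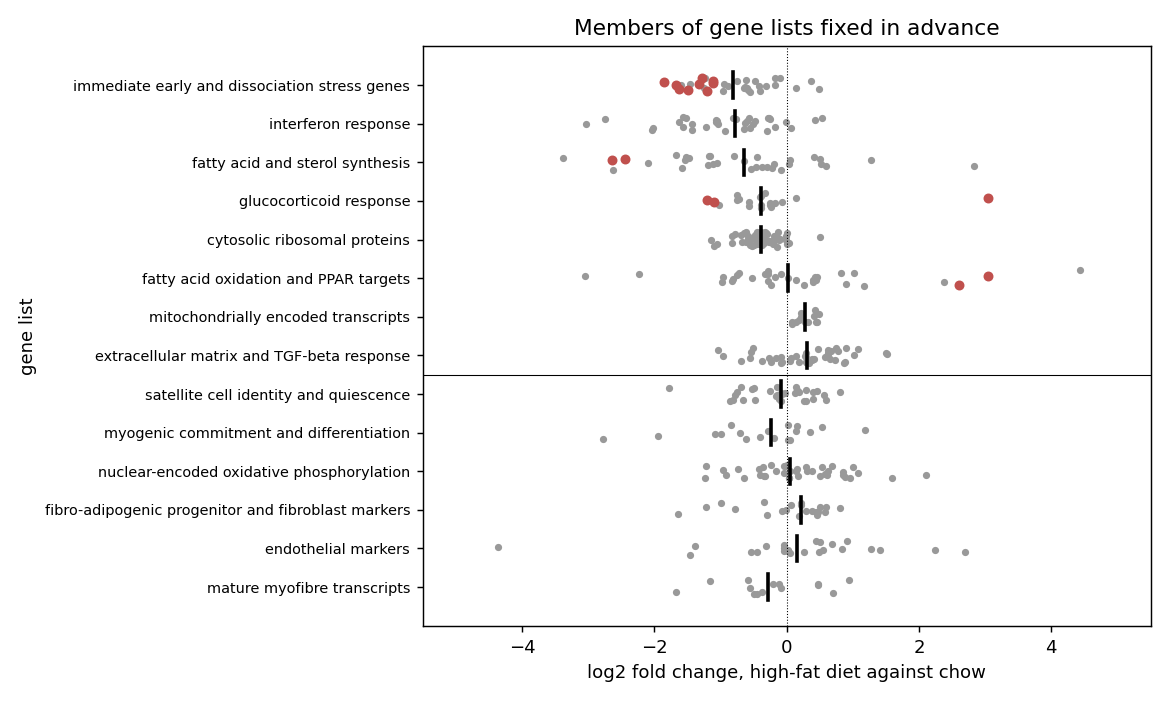
Each point is the log2 fold change (high-fat diet against chow, horizontal axis) of 1 gene in 14 lists, red where it passed over all genes and grey otherwise, with a black bar at the list's median. Above the horizontal line are the 8 lists called by camera, with medians from -0.81 for immediate early and dissociation stress genes to 0.31 for matrix genes, and below it 6 lists that were not called.

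Of 32 lists tested, these 8 were called by camera, 5 lower and 3 higher, and 0 were called with an estimated correlation, where the lowest adjusted p was 0.0793. Fry called 9, of which 7 were shared with camera, and the other 2 were p53 and senescence (adjusted p = 0.0194) and AMPK, sirtuins and mitochondrial biogenesis (adjusted p = 0.0413).

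Markers of satellite cell identity did not pass over all genes in edgeR. Pax7 was at 234 ± 57.3 CPM with the high-fat diet and 402 ± 29.8 CPM with chow (log2 fold change -0.78, SE 0.20, adjusted p = 0.180), Myf5 at 633 ± 158 and 623 ± 102 CPM (0.02, SE 0.19, adjusted p = 1.00), Myod1 at 206 ± 96.8 and 335 ± 54.3 CPM (-0.70, SE 0.27, adjusted p = 0.501) and Myog, a differentiation factor, at 2.17 ± 1.81 and 4.30 ± 1.96 CPM (-0.99, SE 1.54, adjusted p = 0.992). Pax7 passed with DESeq2, limma-voom and no filter. Of the 33 identity and quiescence genes, 0 passed over all genes in edgeR (10 had an unadjusted p under 0.05, and 4 passed with DESeq2 and 2 with limma-voom). Adjusted over the list alone, 2 were higher (Itga7 and Chrdl2) and 6 lower (Hes1, Pax7, Hey1, Tenm4, Spry1 and Col19a1). Camera gave the list an adjusted p of 0.189 (median -0.09). The 27 Notch pathway genes had a median of -0.25 and an adjusted p of 0.133, with 0 passing over all genes in edgeR (4 at an unadjusted p under 0.05, 2 with DESeq2, 1 with limma-voom) and 2 lower adjusted over the list alone. These were the Notch targets Hes1 (99.5 ± 24.1 to 29.1 ± 13.97 CPM, log2 fold change -1.77, SE 0.36, adjusted p = 0.0703 over all genes) and Hey1 (116 ± 6.01 to 66.2 ± 5.97 CPM, adjusted p = 0.232). Hes1 passed with DESeq2, limma-voom, no filter, the replicate number as a block, or without high-fat diet library 3. The 18 genes of commitment and differentiation had a median of -0.24 (adjusted p = 0.387), with 0 passing either way (3 at an unadjusted p under 0.05, 0 with DESeq2 or limma-voom), and the cell cycle inhibitor Cdkn1a had the smallest p (132 ± 26.4 to 73.6 ± 12.9 CPM, adjusted p = 0.279).

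Among metabolic and signalling lists that were not called, single members stood out. In insulin and IGF signalling (adjusted p = 0.793, median -0.04), Igfbp4 rose, and adjusted over the list alone 2 genes were higher, with Igf1 the second, and 4 lower, namely Pik3r1, Irs2, Igf2 and Foxo1. Slc16a3, a lactate exporter in the glycolysis list (adjusted p = 0.771, median -0.02), went from 43.9 ± 11.3 to 120 ± 32.3 CPM (log2 fold change 1.46, SE 0.28, adjusted p = 0.0549 over all genes) and was the 1 member that passed adjusted over the list alone, with 0 passing over all genes in edgeR (3 at an unadjusted p under 0.05, 1 with DESeq2, 1 with limma-voom). In the circadian clock list (adjusted p = 0.0661, median -0.26), the transcriptional repressor gene Bhlhe40 fell 3.01-fold (397 ± 38.3 to 132 ± 28.9 CPM, adjusted p = 0.00323) and was with Nfil3 among 2 lower adjusted over the list alone. The circadian list was called lower without high-fat diet library 2 (adjusted p = 0.0447) or chow library 1 (adjusted p = 0.0272), in a range from 0.0272 to 0.320 over its alternatives. Slc16a3 overlaps Csnk1d, and Bhlhe40 overlaps the noncoding gene 0610040F04Rik. The p53 and senescence list (adjusted p = 0.270, median -0.15) held Btg2, which fell, and 3 members lower adjusted over the list alone (Btg2, Cdkn1a and Gadd45a). AMPK, sirtuins and mitochondrial biogenesis (adjusted p = 0.169, median -0.23) had 0 members passing either way in edgeR, 1 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom.

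The NF-kB and cytokine list (adjusted p = 0.682, median 0.04) had 0 members passing over all genes in edgeR (5 at an unadjusted p under 0.05, 4 with DESeq2, 1 with limma-voom), with 1 higher (Il33) and 4 lower (Tnfaip3, Nfkbiz, Nfkbia and Cxcl10) adjusted over the list alone. The antioxidant list (adjusted p = 0.682, median 0.05) held Mt1, its 1 gene that passed either way in edgeR (3 at an unadjusted p under 0.05, 1 with DESeq2, 2 with limma-voom). The unfolded protein and integrated stress response list (adjusted p = 0.133, median 0.32) had 0 over all genes in edgeR (10 at an unadjusted p under 0.05, 1 with DESeq2, 1 with limma-voom) and Ppp1r15a lower adjusted over the list alone. This last list was called higher without high-fat diet library 3 (adjusted p = 0.00160) or chow library 3 (adjusted p = 0.0361), in a range from 0.00160 to 0.733. Ppp1r15a overlaps Tulp2. No member passed either way in edgeR, nor with DESeq2 or limma-voom, in autophagy and lysosome (adjusted p = 0.189, median 0.26), hypoxia response (adjusted p = 0.843, median -0.13) or Wnt and BMP signalling (adjusted p = 0.473, median -0.18). The same held for replication genes (adjusted p = 0.771, median 0.26), with Ccnd1 at 66.3 ± 21.6 and 130 ± 44.6 CPM, and for mitosis genes (adjusted p = 0.771, median -0.47), with Mki67 at 7.41 ± 7.45 and 28.9 ± 9.17 CPM with chow and the high-fat diet. Both cell cycle lists lay at low levels, with a median of 7.5 CPM for replication (24 of 30 members tested) and 2.5 CPM for mitosis (17 of 32). Their lack of calls is therefore weak evidence of no change. Ccnd1 overlaps LTO1. Median, mean and camera's direction differed in sign for the lists of glycolysis, mitosis, antioxidant, NF-kB, p53, Wnt and BMP, fibroblast, and Schwann and tenocyte genes.

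Markers of other cell types were present in both diets, some at low levels, and with all 6 libraries none of their tested lists was called. Macrophage and monocyte markers had a median of 3.3 CPM (10 of 27 members tested), so their lack of a call is weak evidence of no change. The median log2 fold change was 0.21 for fibro-adipogenic progenitor and fibroblast markers, 0.16 for endothelial cells (adjusted p = 0.843), -0.15 for pericytes and smooth muscle (adjusted p = 0.803), -0.49 for macrophages and monocytes (adjusted p = 0.472), -0.29 for mature myofibres (adjusted p = 0.771), 0.27 for adipocytes (adjusted p = 0.793) and -0.20 for Schwann cells and tenocytes (adjusted p = 0.917). Lymphocyte and neutrophil markers (3 tested, median -0.13) and erythroid and platelet markers (2 tested, median -0.53) were too few to test. The endothelial result depended on high-fat diet library 1, where Pecam1 and Cdh5 were at 4.94 and 6.63 CPM, against 42.0 and 42.0 CPM in high-fat diet library 2 and 41.5 and 65.4 CPM in library 3. Without that library camera called the endothelial list higher with the high-fat diet (median 0.63, adjusted p = 0.00632), as it did without both libraries that stood apart (median 0.96, adjusted p = 1.37e-05). Both calls used the preset correlation of 0.01, though the list's estimated correlation over all 6 libraries was 0.536. They were not repeated with an estimated correlation, so they do not allow for markers that vary together. Over the list's alternatives the adjusted p ran from 1.37e-05 to 0.951. Among the most abundant members, Fabp4, of endothelial cells and adipocytes, was at 86.1 ± 39.7 CPM with the high-fat diet and 63.5 ± 31.6 CPM with chow, Cd68, of macrophages, at 11.4 ± 5.67 and 22.6 ± 7.82 CPM, and Col3a1, of fibroblasts, at 342 ± 55.8 and 361 ± 22.9 CPM. Actn3, of fast myofibres, was at 115 ± 6.61 and 60.0 ± 6.61 CPM, and with Serping1 it was the only such marker to pass adjusted over its list alone, 1 of 14 and 1 of 21, with 0 over all genes in edgeR. Over these 9 marker lists, edgeR called 0 of 113 member entries over all genes, 8 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 2 and 1. Of the 5 sex-linked genes tested, 0 passed (median -0.15).

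Of the remaining named genes, Ksr2, a scaffold protein of the Ras and MAP kinase pathway, had 0 counts in the 3 high-fat diet libraries and 13.1 ± 11.5 CPM with chow (420, 95 and 131 counts), at least 71.9-fold lower against a floor of 3 counts per library (adjusted p = 0.0373). Chow library 1 held most of these counts, and without it the bound was at least 35.7-fold. Ksr2 passed in 0 of the 6 fits with a library left out. Lama3, a chain of basement membrane laminin, fell 3.33-fold (164 ± 34.8 to 49.2 ± 19.6 CPM, adjusted p = 0.0373), though of those fits it passed only the 1 without high-fat diet library 3, with log2 fold changes from -1.94 to -1.43.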

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

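Length and GC corrections, the fit without both libraries that stood apart, and upper-quartile or library-size scaling of the lists were tried only after the results were seen. The count of changed genes (34, with 12 higher and 22 lower) was 33, 35 and 28 with other scalings, 31 with a stricter filter, 43 with robust dispersions, 50 at an adjusted p under 0.1, 35 without mitochondrial genes, 27 with the length correction and 32 with the GC correction. Robust dispersions and the looser threshold gave 19 and 23 higher genes. It was 279 with DESeq2 (117 higher, 162 lower), 99 with limma-voom (44 and 55), 112 with limma-voom and quality weights (48 and 64) and 163 with no filter (72 and 91). It was 6 when tested against a 1.5-fold change (2 and 4) and 1 without both libraries that stood apart (0 and 1), where 4 libraries were left. With 1 library left out it ran from 9 to 44, with 2 to 17 higher and 6 to 27 lower. Those fits had fewer libraries, and the causes of the changes in count were not tested. All 34 genes were called by DESeq2 and 31 also by limma-voom, 8 passed in all 6 fits with 1 library left out and 10 in at least 4, and all 34 kept their sign there. Of the 25 named genes that passed, 25 passed with DESeq2, 24 with limma-voom, 22 with library size alone or the stricter filter, 23 with the block and 20 with the length correction, and of the 36 that did not, 15 passed with DESeq2, 9 with limma-voom and 12 with no filter.

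The labels number the libraries 1 to 3 in each diet without saying that numbers pair them. Deviations of same-numbered libraries from their diet's mean had correlations across genes of 0.0245, 0.0346 and -0.0261, so the numbers were not taken as pairs. With the replicate number as a block, 45 genes passed (17 higher, 28 lower), of which 32 were among the 34, and Ksr2 and Gfra1 were lost. Not every library correlated best with its own number. The lists called stayed at 8.

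The 8 called lists kept their direction and their call under every scaling, without the filter, with the block, with both corrections, without both libraries that stood apart and with each library left out. Those settings, all at the preset correlation, called 8 or 9 lists. The ninth was the endothelial list without high-fat diet library 1 (median 0.63) and without both libraries that stood apart (0.96), the unfolded protein list without high-fat diet library 3 or chow library 3 (0.41 and 0.31), and the circadian list with the length correction or without high-fat diet library 2 or chow library 1 (-0.24, -0.29 and -0.23). Fry kept 7 of them and an estimated correlation 0. Other scalings moved the median log2 fold change of all genes from -0.00809 to between -0.0111 and 0.00766. Reversals touched only results that had not passed. In limma-voom Myf5 was at -0.00433 and Xist at -3.07, and with the block Xist was at -4.77. Camera's direction turned for the endothelial list with the block (median 0.18), for the mitosis, macrophage and adipocyte lists with no filter (-0.43, 0.30 and -0.0550) and for the Schwann and tenocyte list with the length correction (-0.16). Without both libraries that stood apart it turned for the glycolysis (-0.12), NF-kB (0.0719), hypoxia (-0.0146), fibroblast (-0.11) and pericyte (-0.0158) lists. Results that turned with 1 library left out had log2 values from -0.18 to 0.16 for Myf5 and -8.23 to 1.78 for Xist. Medians of the lists that turned there ran from -0.20 to 0.34 for replication, -0.54 to 0.17 for mitosis, -0.15 to 0.0914 for NF-kB, -0.10 to 0.00618 for insulin, -0.00977 to 0.31 for fibroblasts, -0.26 to 0.68 for endothelium, -0.31 to 0.0847 for pericytes, -0.35 to 0.34 for adipocytes and -0.26 to -0.0167 for Schwann cells and tenocytes. The causes were not tested. In simulated data 33% of all genes changed 4-fold were recovered, and above 50 CPM 90.8% of those changed 4-fold and 31.8% of those changed 2-fold. Depth and spread both differ with level and were not varied apart. The gap in correlation within against between diets was 0.0546 with 2000 genes, 0.0107 with all genes and 0.0987 with library size alone.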

Other observations

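The tests of length bias, of heat-shock members and of the sterol against the fatty acid arm were chosen after the result was seen. The other tests were chosen before their own results were seen. The liver X receptor targets and the 5' TOP transcripts were not among the 35 lists fixed before the data were examined.

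Several changed genes lay outside the naming rule and were chosen after their values were seen. Jun fell from 1758 to 809 CPM and Junb from 1273 to 590 CPM (adjusted p = 0.0394 for both, edgeR), Ccn1, a matricellular protein gene, from 394 to 171 CPM (adjusted p = 0.0326) and Csrnp1 from 511 to 253 CPM (adjusted p = 0.0373). Helz2, an interferon-inducible helicase gene, fell from 288 to 145 CPM (adjusted p = 0.0446). Clmn fell from 393 to 171 CPM (adjusted p = 0.00947) and Ifrd1 from 1006 to 521 CPM (adjusted p = 0.0309). Each passed in 4 or fewer of the 6 fits with 1 library left out. Jun, Csrnp1 and Helz2 did not pass with the length correction. Ifrd1 overlaps Mir1938. Among receptors and adaptors of insulin signalling that did not pass over all genes, Irs2 was at 263 CPM with the high-fat diet and 507 CPM with chow (adjusted p = 0.146) and Pik3r1 at 71.1 and 157 CPM (adjusted p = 0.0948).

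The diet split gave 34 changed genes and the highest of the other splits of the 6 libraries 0. Each other split mixes the diets, so a diet difference would widen the spread within its groups and lower its count. For lists the diet split gave 8 and the other splits from 0 to 5. Camera at the preset correlation thus also called lists in splits that mix the diets. In each case 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05.

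For the lower list of immediate early and dissociation stress genes with the high-fat diet (adjusted p = 0.0793 with an estimated correlation), a single library was not the whole cause, since the highest median log2 fold change with 1 library left out was -0.66 against -0.81 with all. Transcript length was not either, since the median after the length correction was -0.82. More handling stress in the chow cells remains a candidate explanation. The 5 heat-shock members of the list, which heat and dissociation also induce, had a median of -1.26 and 4 of 5 were negative, but 0 of 5 passed over all genes in edgeR (1 with DESeq2, 3 with limma-voom), and Hsp90aa1 (0.14, SE 0.15) and Hsph1 (-0.18, SE 0.27) lay within their errors. The labels give no record of sorting day, and Hspa1a and Hspa1b are near-identical copies, so that handling and diet cannot be told apart.

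The list of fatty acid and sterol synthesis was called lower with the high-fat diet at the preset correlation (adjusted p = 0.0793 with an estimated correlation). Leaving out 1 library brought the list's median log2 fold change no higher than -0.52 (all libraries -0.65), and the length correction left it at -0.65, so neither accounts for the whole. The sterol arm had a median of -1.19 and the fatty acid arm one of -0.21, a difference of -0.98, but the arms were divided after these values were seen and their genes are co-regulated, so whether the sterol arm alone fell stays open. Sterol excess in the cells, which would lower these genes and raise targets of the liver X receptors, could not be decided, as 9 such targets had a median of 0.22 (camera p = 0.122, or 0.350 with an estimated correlation). Obesity itself stays open as an untested cause.

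For the slightly lower ribosomal protein genes with the high-fat diet (adjusted p = 0.159 with an estimated correlation), the median log2 fold change stayed at or below -0.33 with any 1 library left out (all libraries -0.39). A trend with transcript length does not account for the whole, since the median after the length correction was -0.386. Lower levels of 5' TOP transcripts as a class, whose shared leader motif ties them to growth signalling, are a hypothesis. Of 15 other such transcripts, 12 were negative, the median was -0.30 and limma's camera gave an adjusted p of 0.00311 over this list and the liver X receptor targets. The support is weak, since with an estimated correlation p = 0.197 and reads shared with pseudogenes were not excluded.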
